A study of Homo sapiens with 8 samples.

How the data were processed

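The libraries were made from polyadenylated RNA with a stranded mRNA kit, per the labels' protocols, from input RNA or from RNA immunoprecipitated with the J2 antibody. The submitters' processing notes name HISAT2 2.0.4 and the builds mm10 and hg38. They name no counting program, strand setting or choice of introns. Each deposited file lists the same 142224 introns, with 1 RefSeq transcript per gene and 15902 genes, and carries no header. For 15510 genes the RefSeq transcript was linked to a GENCODE 29 transcript, and the linked transcript that shared most introns was taken. Of 138757 listed introns of these genes, 138297 matched an intron of that transcript on GRCh38. The listed introns made up 85.6% of the 162045 introns of those transcripts. Single-exon genes and mitochondrial transcripts are not listed, so the planned comparison of single-exon with multi-exon genes and the mitochondrial share were not analysed here.

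The deposited files hold 3 values per intron. The first is a whole-number read count deposited without normalization, taken as reads inside the intron. The second deposited count is never below the first, and its excess was taken as reads spliced across the intron. No header states this, and it was inferred from the values. The excess was alike in neighbouring introns of a gene (Spearman correlation 0.953, against 0.303 for intronic reads). It hardly rose with the length of the shorter flanking exon among introns whose flanking exons had at least 100 bases (slope 0.0860, 20527 introns), where exonic reads would rise with it. The last deposited value is an RPKM that the authors computed from the first count, the intron length and a whole-number depth per library. Those depths were 48000000 and 51000000 reads for input with vehicle, 47000000 and 48000000 for input with drug, 53000000 and 57000000 for J2 with vehicle, and 50000000 and 53000000 for J2 with drug. Of the listed introns, 18 of at most 9 bases lack the last 2 values and were left out, which left 142206. Introns over 1 RPKM made up 3.05% of those that overlap an exon of another gene on the same strand and 1.64% of those with such an exon on the other strand. They made up 0.674% of those free of other exons. That last class also leaves out introns with another exon of the same gene, so the classes are not fully alike. Reads of an antisense gene were therefore treated as not separable.

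The design assumed TPM and limma, with edgeR's quasi-likelihood test if the files held counts. They held counts, so edgeR 4.0.16 was used for intronic and for spliced reads summed per gene, with the depth behind the RPKM as library size. The intronic to spliced ratio of a gene was tested with limma 3.58.1 on log2 of intronic reads + 1 over spliced reads + 1. All 8 libraries entered 1 fit with 4 group means. Genes were kept with at least 1 RPM in at least 2 libraries, which left 8461 genes for spliced reads, 3992 for intronic reads and 3837 for the ratio. The comparisons were drug against vehicle in the input and in J2 RNA, J2 against input with vehicle and with drug, and the interaction, which is the drug effect in J2 RNA minus that in the input. The p-values were adjusted with Benjamini-Hochberg over all genes of a comparison and measure, with a threshold of 0.05.

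Gene lists, 23 in all, were fixed before the data were examined. They cover the SF3b complex, other spliceosome components, SR and hnRNP regulators, interferon-stimulated genes, interferons, double-stranded RNA sensing and handling, NF-kB and cytokine genes, intronless genes, histone genes and mitochondrial transcripts. They also cover the integrated stress and unfolded protein responses, apoptosis regulators, p53 targets, mitotic genes, DNA replication and repair, immediate-early genes, genes reported with edited Alu repeats, ribosomal protein genes, nonsense-mediated decay factors, mesenchymal, luminal and immune markers, and long noncoding RNAs. Lists with fewer than 5 tested members (interferons 0, intronless 2, histones 1, mitochondrial 0, luminal 4, immune 1, noncoding 0 for spliced reads) were not analysed here. The others were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison and measure. An estimated correlation and fry were alternatives, and members were also counted as adjusted over the list alone.

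Genes named in the text follow a rule. For both drug effects and the interaction these were up to 10 genes each way, and for both comparisons of J2 with input up to 5 each way. They had the largest log2 fold change past the threshold, at least 5 RPM in 1 of the groups compared, a protein-coding symbol and the same sign in every pair of libraries. Up to 4 members per list with the smallest p and SF3B1, ADAR, IFIH1, DDX58 and MCL1 were added. SLCO5A1 and HFM1 were singled out after their values were seen. A fold change against a group without reads is given as a lower bound from a floor of 3 counts over the group, and with 1 to 3 reads as a ratio with its 95% interval.

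The tests were run on simulated counts drawn from 1 mean per gene over all 8 libraries and from their depths. In the input drug libraries 200 genes were changed, and drug was set against vehicle in the input. These counts held no general shift, unlike the data, where 78.3% of genes tested rose in intronic reads with drug in the input. They therefore show recovery only where few genes change. Of 8102 genes with spliced reads, edgeR recovered 95 of 100 changed 2-fold and 100 of 100 changed 4-fold, with 5 false calls. Of 3362 genes with intronic reads it recovered 98 of 100 and 100 of 100, with 5 false calls. For the ratio, over 3133 genes, limma recovered 86 of 94 and 95 of 95, with 12 false calls. In camera, a raised list of 40 genes was called and none of 20 unchanged lists was. In the data, replicates differed beyond sampling noise (chi-square per degree of freedom 2.79 to 60.6 over groups and measures).

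The alternatives, whose effects are given with the other results on processing, were another scaling (median-of-ratios or TMM), DESeq2 1.42.0, limma on log2 of RPM + 1, the deposited RPKM, a minimum of 5 RPM or no filter, a pseudocount of 0.1, a fit without trend, and a fit on the compared groups alone. Others were a replicate block, introns of at least 100 bases, introns free of other exons, and each library left out in turn. Correlations across genes are descriptive. Introns free of other exons numbered 110720. Exons of retained-intron transcripts of the same gene were not counted as other exons there. R 4.3.3 with the package data.table (version 1.17.8), Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Matplotlib 3.10.9 and bedtools 2.31.1 were used.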

Results

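The series holds 8 RNA sequencing libraries from SUM159, an established human triple-negative breast cancer cell line with mesenchymal features. Cells were treated for 12 h with H3B-8800, a small molecule that binds the SF3b complex of the spliceosome, or with the solvent DMSO as vehicle. RNA was sequenced either directly (input) or after immunoprecipitation with J2, an antibody against double-stranded RNA. The 4 groups, input with vehicle, input with drug, J2 with vehicle and J2 with drug, held 2 biological replicates each. None is an immunoprecipitation with a control antibody, so differences between J2 RNA and input are not shown to come from double-stranded RNA. Recovery by J2 means depth-scaled reads in J2 RNA relative to the input, not an absolute amount. Each library came with a table of 142224 introns in 15902 genes, with reads inside each intron and a larger total whose excess was read as reads spliced across the intron. Over all introns the input libraries held 12612577 and 13548343 reads with vehicle and 12679980 and 13562705 with drug. The J2 libraries held 13795626 and 14643731 reads with vehicle and 13062067 and 13783595 with drug. Values in RPM are reads per 1000000 of the library depths behind the deposited RPKM, which ran from 47000000 to 57000000 reads. They are given as mean ± SD (n = 2 libraries), and log2 fold changes as value ± SE. For edgeR this SE is the size of the log2 fold change over the square root of the test's F value. It is not a separately estimated error, and it may be too small where a group held few reads. Counting intervals and floors cover counting error only, because the reads carry no molecular identifiers.

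The drug raised the part of the reads that lay inside introns, the direct readout of a splicing inhibitor. Intronic reads made up 3.82% ± 0.0136 (SD, n = 2) of intronic and spliced reads in the input with vehicle and 11.6% ± 1.96 with drug. In J2 RNA the shares were 3.80% ± 0.248 with vehicle and 12.7% ± 0.292 with drug. These and all further intronic shares count reads anywhere inside an intron, without correction for its length. They are not the fraction of transcripts that keep the intron. A further set held 110720 introns free of other annotated exons, apart from exons of the same gene's retained-intron transcripts. There the shares were 1.67% and 8.44% in the input and 1.39% and 9.18% in J2 RNA. The wide spread of the input with drug came from 2 introns, in SLCO5A1, a solute carrier gene, and HFM1, a meiotic helicase gene. They held 270846 and 142699 reads in replicate 1 and 26020 and 14052 in replicate 2, and without them the share was 10.05% ± 0.0741. Both drug libraries lay above both vehicle libraries in each kind of RNA. With 2 libraries against 2, an exact permutation test cannot fall below p = 0.333 (two-sided), so these shares are given without a test.

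**Figure D1:**
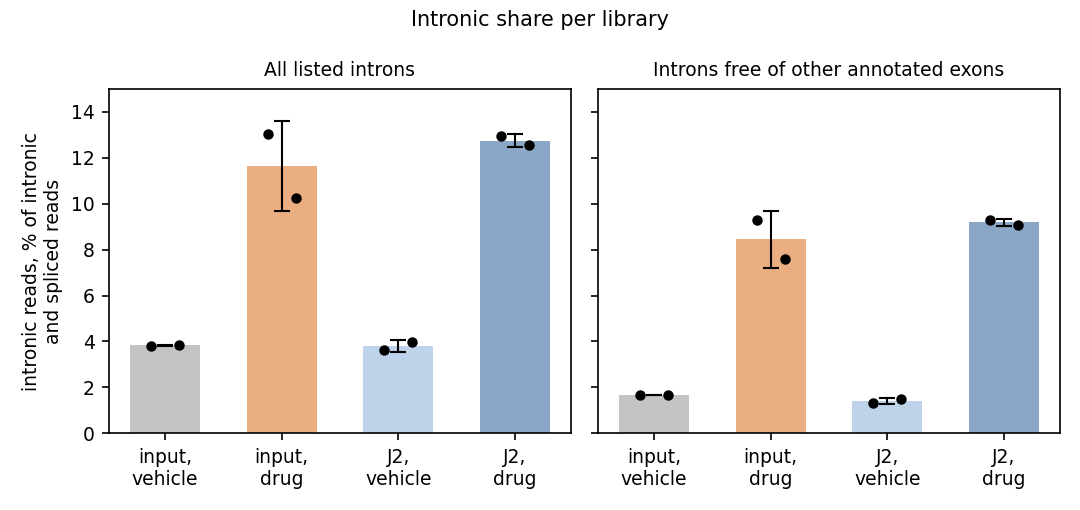
Intronic reads as percent of intronic and spliced reads in each library (points), with group means (bars) and SD over 2 libraries (error bars), over all listed introns and over introns free of other annotated exons. Over all listed introns, vehicle groups averaged 3.82% and 3.80% and drug groups 11.6% and 12.7%.

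The first comparison asked what the drug did to RNA before enrichment. AP2S1, which encodes a subunit of the clathrin adaptor, had no intronic read in 2 vehicle libraries and 672 with drug, at least 233-fold more against a floor of 3 counts over the group. All of them lay in its only listed intron (chromosome 19, 46838549 to 46838739, GRCh38, intron 4 of 4), which was 35.8% intronic with drug. SRP14, a subunit of the signal recognition particle, rose from 0.1299 ± 0.0659 to 17.5 ± 0.186 RPM of intronic reads (log2 fold change 7.03 ± 0.20, edgeR with Benjamini-Hochberg adjusted p = 1.83e-21, and 7.67 without input vehicle replicate 2). AURKB, a mitotic kinase, rose from 0.154 ± 0.107 to 18.6 ± 1.41 (6.92 ± 0.21), and its intron 7 of 8 (chromosome 17, 8205391 to 8206490) went from 0% to 77.4% intronic. LMNB2, a nuclear lamin, rose from 0.366 ± 0.101 to 30.1 ± 0.314 (6.36 ± 0.16), with its last intron (chromosome 19, 2430953 to 2431547, intron 11 of 11) going from 2.83% to 92.3% intronic. Further large rises were in WSB2, a ubiquitin ligase adaptor (7.16), YY1, a transcription factor (6.47), and MAPRE1, a microtubule end-binding protein (6.33). Without input vehicle replicate 1 or 2 the log2 fold changes were 7.85 and 6.33 for AURKB and 8.21 and 5.67 for YY1. CDK4, a cyclin-dependent kinase, rose by a log2 fold change of 6.81 in an intron that overlaps TSPAN31 on the other strand. KIAA1467 had 975 intronic reads with drug against 2 with vehicle (ratio 508, 95% interval 140.3 to 4201), but 946 of them lay in intron 1 in replicate 1.

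Falls in intronic reads were few. CPAMD8, a protease inhibitor family gene, fell from 9.64 ± 0.513 to 0.199 ± 0.0715 RPM (-5.57 ± 0.23, edgeR with Benjamini-Hochberg, adjusted p = 4.70e-18). MTHFD2, a mitochondrial folate enzyme, fell from 5.26 ± 0.483 to 1.24 ± 0.279 (-2.08 ± 0.20), PCBP2, a poly(C)-binding protein, had a log2 fold change of -2.04, and SLC37A1, a sugar-phosphate transporter, of -1.57. Of 3992 genes tested, intronic reads of 3127 rose and of 260 fell, with a median log2 fold change of 1.73. Drug libraries alone could bring a gene past the filter of 1 RPM in 2 libraries. That favours rises in these counts and medians, here and in J2 RNA. Median-of-ratios scaling, which moves nearly all genes by the same amount so that the median lies near 0 (0.05), gave 1340 rises and 1366 falls. Its counts, here and further on, are of genes above and below that common shift by construction and test no direction. In fixed gene lists, 34 of 40 ribosomal protein genes rose and 2 fell, with the same counts adjusted over the list alone. The list stood above other genes by limma's camera (adjusted p = 0.000888, and adjusted p = 0.343 with an estimated correlation), and under median-of-ratios scaling 17 rose and 14 fell. Of 14 other spliceosome genes 12 rose and none fell, of 9 mitotic genes all 9 rose, and of 7 NF-kB and cytokine genes all 7 rose, with 8 and 4, 8 and 0, and 4 and 1 rising and falling under median-of-ratios scaling. These lists did not stand apart from other genes (adjusted p = 0.117, 0.117 and 0.804).

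Retention, the intronic to spliced ratio of a gene, does not depend on library depth, and it rose in most genes tested. The genes tested, 3837 against 8461 for spliced reads, needed at least 1 RPM of intronic reads in at least 2 libraries. Drug libraries alone could meet that. KTN1, a kinesin receptor, went from 1.11% ± 0.354 to 77.3% ± 3.57 intronic reads (8.21 ± 0.34, limma with Benjamini-Hochberg, adjusted p = 1.72e-08). USP1, a deubiquitinase of DNA repair, went from 6.37% ± 1.09 to 93.8% ± 0.186 (7.65 ± 0.27), and INF2, an actin-nucleating formin, from 3.82% ± 0.927 to 87.4% ± 0.831 (7.44 ± 0.15), most of it in intron 2 of 22 (chromosome 14, 104701757 to 104703104). NUDT22, a hydrolase gene (1.28% to 66.04%), overlaps the antisense RNA AP001453.1, so its reads were not assigned with certainty. The ratio fell in SRSF3, a splicing regulator, from 32.1% ± 1.84 to 9.18% ± 0.537 (-2.23 ± 0.11, limma with Benjamini-Hochberg, adjusted p = 5.48e-08), in intron 3 of 5 (chromosome 6, 36598984 to 36601151), which contains an exon of another SRSF3 transcript. Of 3837 genes tested the ratio rose in 3212 and fell in 88, with a median of 2.30, against 1314 and 1208 when intronic and spliced reads were each scaled by median-of-ratios. The nonsense-mediated decay factors rose in 8 of 8 cases, among them the helicase UPF1 (4.61), and double-stranded RNA sensing genes in 11 of 12, with 3 and 1 and 4 and 3 rising and falling under that scaling. Of 15 SR and hnRNP regulators 9 rose, such as PTBP1 (3.34) and HNRNPL (2.84), and 3 fell, against 5 and 7 relative to the common shift. Of 40 ribosomal protein genes 27 rose, such as RPS28 (4.81) and RPL30 (3.37), and 3 fell, against 9 and 23 relative to that shift. Counts adjusted over the list alone were the same in these 4 lists, and no list stood apart from other genes by camera (smallest adjusted p = 0.0750).

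Spliced reads fell in more genes than they rose. PLEKHJ1, an endosomal protein gene, fell from 42.9 ± 1.75 to 1.67 ± 0.347 RPM (-4.68 ± 0.12, edgeR with Benjamini-Hochberg, adjusted p = 5.98e-09). SLC35C2, a nucleotide sugar transporter, fell from 21.3 ± 1.25 to 0.991 ± 0.223, ASNS, asparagine synthetase, from 8.74 ± 0.0971 to 0.411 ± 0.0806, MKS1, a ciliary protein, from 10.3 ± 0.456 to 0.516 ± 0.03699, and PARP10, an ADP-ribosyltransferase, from 11.4 ± 0.0277 to 0.599 ± 0.0953. USP10, a deubiquitinase, rose from 9.15 ± 0.292 to 45.3 ± 2.72 (2.31 ± 0.10), and GUCA1B, a guanylate cyclase activator, from 0.466 ± 0.0771 to 6.34 ± 0.124 (3.76 ± 0.18). GAREM, an adaptor of growth factor signalling, rose from 0.162 ± 0.00693 to 14.7 ± 3.56 (6.49 ± 0.26), in a gene whose intron 1 holds the pseudogene HNRNPA1P7. Of 8461 genes tested 1841 rose and 4118 fell, with a median of -0.38, against 3178 and 2914 with median-of-ratios scaling (median 0.03).

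Genes of the splicing machinery went against this trend. Of 6 genes of SF3b, the drug's target, 5 rose and 1 fell, for example SF3B3 (1.22 ± 0.08) and PHF5A (1.17 ± 0.11), while DDX42 had -1.03 ± 0.10. Of 35 other spliceosome genes 20 rose, such as SNRPD1 (1.63 ± 0.08) and SNRPB (1.06 ± 0.05), and 8 fell, against 27 and 5 with median-of-ratios scaling. Of 28 SR and hnRNP regulators 15 rose, among them SRSF3 (55.7 ± 1.77 to 162 ± 21.01 RPM), and 6 fell, among them HNRNPU (-1.83 ± 0.09), against 18 and 4. Of 47 ribosomal protein genes 40 rose, such as RPL10 (1.36 ± 0.11) and RPS13 (1.01 ± 0.08), and 1 fell, against 46 and 1. Of 28 mitotic genes 11 rose, such as the kinase PLK1 (1.29 ± 0.06) and the transcription factor FOXM1 (1.03 ± 0.07), and 7 fell, such as TOP2A, a topoisomerase (-2.84 ± 0.22), against 16 and 5. Adjusted over the list alone, 21 spliceosome genes rose and the other counts were the same. By camera these 5 lists stood above other genes (adjusted p = 0.0153, 1.00e-05, 0.00474, 4.21e-12 and 0.0238), a call that none kept with an estimated correlation (adjusted p = 0.681 each).

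Genes that respond to interferon mostly fell in spliced reads. These count only reads spliced across introns, so a fall does not by itself show less RNA of the gene. Of 25 interferon-stimulated genes none rose and 20 fell, the same adjusted over the list alone, for example IFI35 (-2.38 ± 0.08), IRF1 (-1.48 ± 0.07), ISG20, an exonuclease (-2.62 ± 0.20), and EPSTI1 (-1.78 ± 0.13). The list lay below other genes by camera (adjusted p = 0.0260, and adjusted p = 0.681 with an estimated correlation), and median-of-ratios scaling gave 6 rises and 15 falls. Of 17 NF-kB and cytokine genes 3 rose and 11 fell, among them NFKB2 (-2.81 ± 0.08) and RELB (-2.14 ± 0.10), against 5 and 8. Of 24 integrated stress and unfolded protein response genes 5 rose and 13 fell, among them ASNS (-4.40 ± 0.25) and SHMT2, a serine metabolism enzyme (-1.48 ± 0.06), against 10 and 8. Of 22 genes that sense or handle double-stranded RNA 6 rose and 10 fell, against 9 and 8. These 3 lists did not stand apart from other genes by camera (adjusted p = 0.360, 0.726 and 0.726). ADAR, which edits double-stranded RNA, rose from 23.4 ± 1.02 to 35.4 ± 3.66 RPM (0.60 ± 0.09, edgeR with Benjamini-Hochberg, adjusted p = 0.000207). The sensor IFIH1 fell in spliced reads from 2.33 ± 0.328 to 0.629 ± 0.318 (-1.88 ± 0.37, edgeR, adjusted p = 0.00137, and -2.52 without input drug replicate 2). Its intronic reads rose from 0.852 ± 0.179 to 2.66 ± 0.486 RPM (1.64 ± 0.27, edgeR, adjusted p = 4.32e-06), near the median of tested genes (1.73). Its intronic share went from 26.7% to 80.6%, so a lower amount of IFIH1 RNA is not shown. The sensor DDX58 fell from 2.64 ± 0.484 to 1.44 ± 0.05297 (-0.87 ± 0.31, edgeR, adjusted p = 0.02902). That call ended without input vehicle replicate 1 (-0.67, adjusted p = 0.176), input drug replicate 1 (-0.83, adjusted p = 0.1198) or input drug replicate 2 (-0.91, adjusted p = 0.0964), and with median-of-ratios (-0.46) or TMM scaling (-0.59) or DESeq2 (-0.46). SF3B1, the drug-binding subunit, had only 3 listed introns and 0.929 ± 0.0173 RPM of spliced reads with vehicle and 0.787 ± 0.3604 with drug, too few to test. MCL1, interferon genes, histone genes, mitochondrial transcripts and genes without introns were not analysed here, because the files list none of their introns or fewer than 5 tested genes.

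**Figure D2:**
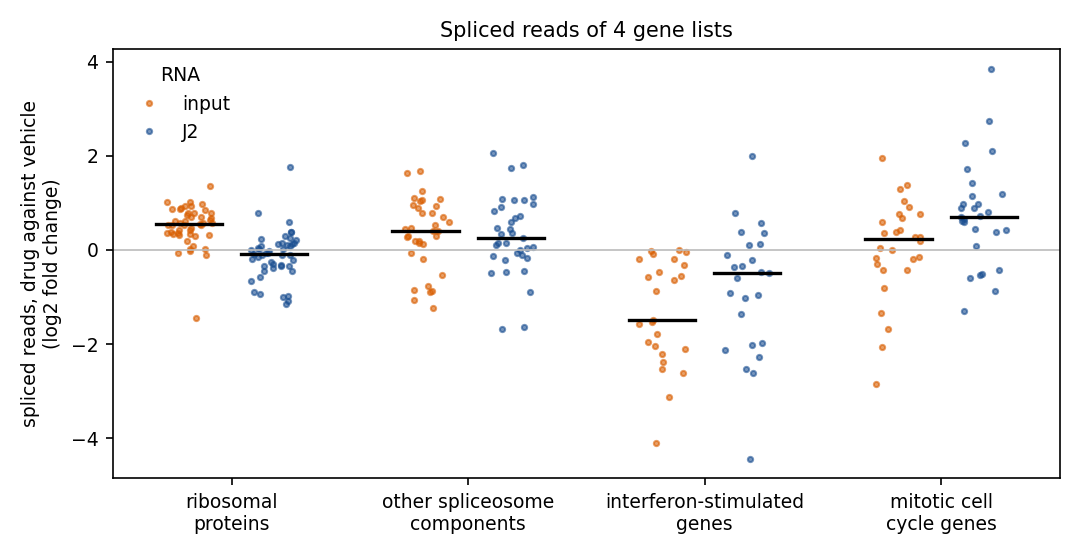
Spliced reads with drug against vehicle (log2 fold change, depth scaling) for each tested member of 4 gene lists (points) in the input and in J2 RNA, with list medians (black lines). In the input 40 of 47 ribosomal protein genes rose and 20 of 25 interferon-stimulated genes fell, against 46 and 15 with median-of-ratios scaling.

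The second comparison asked what the drug did to RNA recovered with J2. Intronic reads of AP2S1 went from 1 with vehicle to 1138 with drug (ratio 1215, 95% interval 217.7 to 48045). SRP14 rose from 0.119 ± 0.0447 to 32.4 ± 0.176 RPM (8.07 ± 0.19, edgeR with Benjamini-Hochberg, adjusted p = 2.89e-23), and SYF2, a splicing factor, from 0.0728 ± 0.00375 to 16.3 ± 0.505 (7.76 ± 0.23). TLE3, a transcriptional corepressor, had 543 intronic reads with drug and 3 with vehicle (ratio 193, 95% interval 65.8 to 940.3). CPAMD8 fell from 12.9 ± 0.957 to 0.333 ± 0.124 (-5.27 ± 0.21), VTI1A, a vesicle fusion protein, from 6.93 ± 1.24 to 0.8996 ± 0.312 (-2.95 ± 0.24), and SRSF3 from 36.6 ± 0.726 to 8.802 ± 1.24 (-2.06 ± 0.10). Of 3992 genes 3342 rose and 229 fell (median 2.20, and 1422 and 1390 with median-of-ratios scaling, median 0.05). Of 40 ribosomal protein genes 35 rose and none fell, the same adjusted over the list alone, against 16 and 14 under that scaling (camera adjusted p = 0.00824, and adjusted p = 0.476 with an estimated correlation).

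The intronic to spliced ratio in J2 RNA rose in TNIP2, an NF-kB inhibitor, from 3.23% to 90.2% intronic (8.10 ± 0.17), and in NADK, the NAD kinase, from 1.97% to 74.3% (7.14 ± 0.09). It rose in KLF4, a transcription factor, from 0.871% to 26.9% (5.37 ± 0.25), and in RPL30 from 2.66% ± 0.0213 to 58.6% ± 2.504 (5.69 ± 0.09, limma with Benjamini-Hochberg, adjusted p = 8.42e-11). It fell in SRSF3 from 33.9% ± 0.581 to 9.695% ± 0.651 and in C6orf62, a gene of unknown function, from 72.3% ± 2.21 to 35.8% ± 6.804. Of 3837 genes 3203 rose and 131 fell (median 2.44), against 1337 and 1296 with median-of-ratios scaling. All 9 mitotic genes rose, as did 13 of 14 other spliceosome genes, such as PRPF6 (4.70), with 5 and 0 and 7 and 5 rising and falling under that scaling. No list stood apart by camera (smallest adjusted p = 0.710).

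Spliced reads in J2 RNA rose in 2927 and fell in 3344 of 8461 genes (median -0.03, and 3214 and 3142 with median-of-ratios scaling). The effect went with transcript GC content (Spearman -0.448 across 8283 genes), and 74.8% of rises and 72.6% of falls were kept with each library's trend over GC content and length removed. HDX, a homeobox gene, rose from 0.184 ± 0.0866 to 6.11 ± 0.691 RPM (5.05 ± 0.33), AMD1, a polyamine synthesis enzyme, from 0.593 ± 0.0948 to 10.4 ± 5.93 (4.12 ± 0.42, edgeR with Benjamini-Hochberg, adjusted p = 1.54e-05, and 3.37 without J2 drug replicate 2), and PRPF39, a splicing factor, from 0.749 ± 0.141 to 12.7 ± 4.61 (4.08 ± 0.28). PLEKHJ1 fell from 55.5 ± 1.74 to 2.63 ± 0.0702 (-4.40 ± 0.11) and LRSAM1, a ubiquitin ligase, from 18.6 ± 2.16 to 0.989 ± 0.0416 (-4.23 ± 0.15). Of 28 mitotic genes 20 rose, such as BIRC5, an apoptosis inhibitor (1.15 ± 0.08), and 6 fell, such as CDC20 (-1.31 ± 0.07). Of 25 interferon-stimulated genes 3 rose and 16 fell, such as XAF1 (-2.62 ± 0.18). Ribosomal protein genes divided, with 9 rising, such as RPS28 (0.79 ± 0.06), and 20 falling, such as RPL28 (-1.14 ± 0.07), against 15 and 16 with median-of-ratios scaling. In double-stranded RNA sensing genes 9 rose, among them DDX58 (1.88 ± 0.33, from 0.6399 ± 0.136 to 2.35 ± 0.947 RPM), and 7 fell. Adjusted over the list alone, 6 sensing genes fell and the other counts were the same. No list passed by camera (smallest adjusted p = 0.108).

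The drug effects in input and in J2 RNA, which share no library, followed each other for intronic reads across genes (Pearson 0.854, Spearman 0.866, 3992 genes that are not independent replicates). In all, 3010 genes rose in both and 152 fell in both, where independent lists would share 2618 and 15. The genes with opposite calls numbered 39. For spliced reads the correlation was lower (Pearson 0.588, Spearman 0.566), with 1228 shared rises and 2687 shared falls, against 637 and 1628 for independent lists, and 797 opposite calls.

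**Figure D3:**
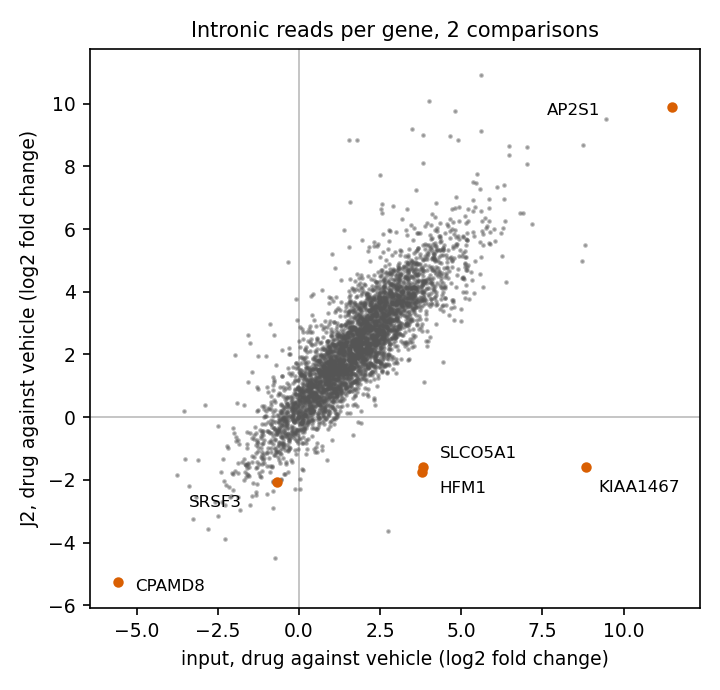
Intronic reads per gene, drug against vehicle, in the input (horizontal axis) and in J2 RNA (vertical axis), both as log2 fold change, with 1 point per tested gene (3992). AP2S1, with 0 or 1 read with vehicle, lies at the upper right, and SLCO5A1, HFM1 and KIAA1467 depart from the diagonal.

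The effect was also read by intron structure, over 20996 introns free of other exons with at least 20 reads over the intron in every library. The share of introns with at least 10% intronic reads went from 6.18% to 24.7% in the input and from 5.06% to 22.9% in J2 RNA. Introns under 100 bases (2050 introns) went from 2.54% to 23.7% in the input, and those of 20000 bases and over (276 introns) from 22.3% to 27.2%. Over the 8 length classes the input ran from 1.97% to 22.3% with vehicle and from 20.3% to 30.04% with drug. A longer intron has more room for intronic reads at equal retention, and the shares were not corrected for this. Differences between classes of intron therefore do not measure retention, while drug and vehicle are compared over the same introns. Among introns of at least 500 and under 2000 bases, the last intron of a transcript (942 introns) went from 1.98% to 10.4% intronic reads in the input, internal introns (5596) from 1.21% to 7.06%, and first introns (297) from 2.00% to 5.34%. Across 8283 genes, which are not independent replicates, genes with more introns had lower spliced log2 fold changes with drug in the input (Spearman -0.264), a trend not seen in J2 RNA (-0.0140). The number of introns went with a higher intronic to spliced ratio with drug (0.169 in the input and 0.0761 in J2 RNA, 3752 genes). For intronic reads alone the correlations were 0.0470 in the input and 0.0750 in J2 RNA (3898 genes). The spliced trend of the input enters its ratio, so the ratio is not a separate sign of more retention there.

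**Figure D4:**
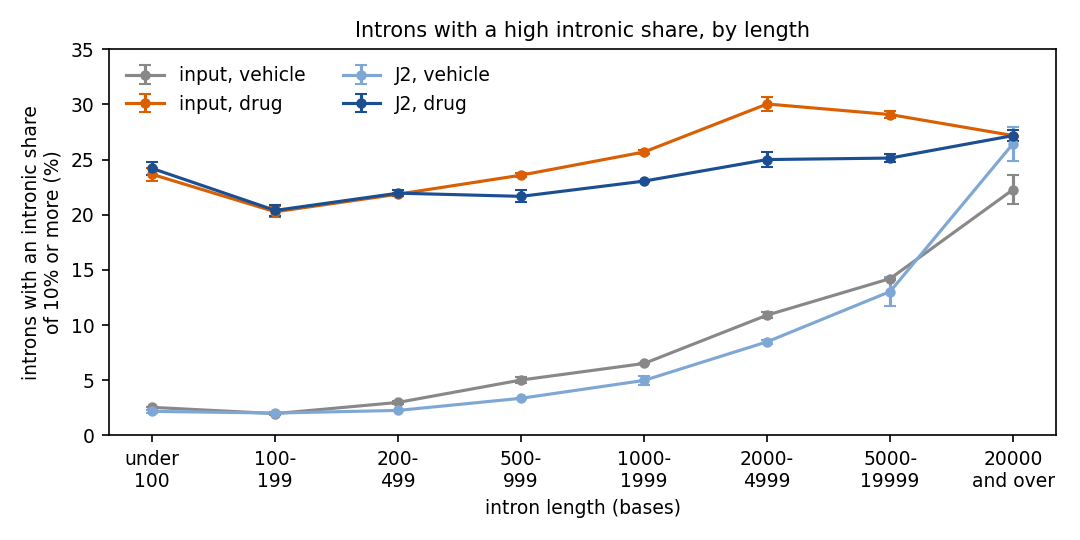
Percent of introns with at least 10% intronic reads (vertical axis) by intron length in bases (horizontal axis), as the mean of each group with SD over 2 libraries (error bars), over introns free of other exons. Intronic shares were not corrected for intron length. Introns under 100 bases went from 2.54% to 23.7% in the input with the drug, and those of 20000 bases and over from 22.3% to 27.2%.

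The third comparison asked which RNAs were higher or lower in J2 RNA than in the input without the drug. ARPC1A, a subunit of the actin-nucleating complex, went from 36.5 ± 0.506 RPM of spliced reads in the input to 132 ± 2.42 in J2 RNA (1.86 ± 0.07, edgeR with Benjamini-Hochberg, adjusted p = 3.01e-07). EIF3F, a translation initiation factor, went from 69.5 ± 0.151 to 225 ± 5.04, CRADD, an apoptosis adaptor, from 13.02 ± 0.444 to 44.9 ± 1.06, and RPS27A, a ubiquitin fusion gene, from 143 ± 3.16 to 471 ± 33.8. NBPF14 rose by 2.41 ± 0.36 but belongs to a multicopy family, so its reads were not assigned with certainty. RPL39, a ribosomal protein gene, went from 50.4 ± 3.88 to 1.32 ± 0.112 (-5.24 ± 0.52), IL6ST, a cytokine receptor, from 31.8 ± 0.005199 to 1.73 ± 0.3097 (-4.20 ± 0.24), and AHNAK2, a large scaffold protein, from 12.99 ± 0.601 to 0.906 ± 0.133 (-3.84 ± 0.15). In intronic reads, SDCCAG3, an endosomal protein gene, went from 1.56 ± 0.176 to 6.62 ± 0.881 (2.08 ± 0.14), and RPS12, whose intron hosts SNORD101, from 6.21 ± 0.448 to 25.2 ± 0.177 (2.02 ± 0.11). VEGFA, an angiogenic growth factor, went from 9.299 ± 0.187 to 0.755 ± 0.02598 (-3.62 ± 0.18), with its intron 3 of 6 (chromosome 6, 43777666 to 43778459) going from 35.3% to 5.09% intronic. The intronic share of ERN1, a stress sensor of the endoplasmic reticulum, rose from 24.3% to 77.5% (3.42 ± 0.14, limma with Benjamini-Hochberg, adjusted p = 2.90e-06).

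Integrated stress response genes had lower intronic reads in J2 RNA, with 9 of 12 down and none up, and so did other spliceosome genes, with 9 of 14 down (10 adjusted over the list alone) and none up. Under median-of-ratios scaling each list had 1 up and 7 down. Both lay below other genes by camera (adjusted p = 0.00430 each, and adjusted p = 0.241 each with an estimated correlation). The intronic to spliced ratio fell in 9 of the 12 stress genes (10 adjusted over the list alone), such as DDIT4 (-1.78 ± 0.22), SESN2 (-2.24 ± 0.32) and TRIB3 (-2.02 ± 0.29), and in 9 under that scaling (camera adjusted p = 0.00162, and adjusted p = 0.403 with an estimated correlation). In spliced reads no list passed (smallest adjusted p = 0.381). Of 8461 genes 1386 rose and 3746 fell in spliced reads (median -0.28), against 3049 and 2280 with median-of-ratios scaling (median 0.10). This recovery went with transcript GC content (Spearman 0.479 across 8283 genes). With each library's trend over GC content and length removed, 34.6% of rises and 78.9% of falls were kept, or 48.3% and 70.7% with the median effect held as before, and whether the genes named here kept theirs was not analysed here. Of 3992 genes 313 rose and 1174 fell in intronic reads (median -0.37, and 856 and 539, median 0.08). Of 3837 genes 424 rose and 806 fell in the ratio (median -0.20, and 643 and 483, median 0.05), and the falls were 532 without input vehicle replicate 1.

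The fourth comparison asked the same with the drug. AMD1 went from 1.07 ± 0.269 RPM of spliced reads in the input to 10.4 ± 5.93 in J2 RNA (3.28 ± 0.40, and 2.53 without J2 drug replicate 2), and SNX5, a sorting nexin, from 4.13 ± 0.311 to 36.3 ± 13.9 (3.13 ± 0.23). RPS29, a ribosomal protein gene, went from 181 ± 39.5 to 9.83 ± 2.51 (-4.21 ± 0.19, edgeR with Benjamini-Hochberg, adjusted p = 3.80e-07), and the receptor gene NOTCH2 from 30.1 ± 2.83 to 2.84 ± 0.872 (-3.40 ± 0.18). Of 47 ribosomal protein genes 33 were lower in J2 RNA, such as RPL37 (-2.90 ± 0.10) and RPL12 (-2.38 ± 0.06), and 7 higher (8 adjusted over the list alone). Of 35 other spliceosome genes 21 were lower, such as SF1 (-1.30 ± 0.08), and 2 higher. Of 6 SF3b genes 5 were lower (6 adjusted over the list alone), such as SF3B2 (-0.90 ± 0.05), and none higher. Of 14 mesenchymal markers 8 were lower, such as FN1, fibronectin (-2.68 ± 0.12), and none higher. Median-of-ratios scaling moved the counts of higher and lower genes to 8 and 31, 3 and 20, 0 and 5, and 1 and 8. The 4 lists passed by camera (adjusted p = 4.09e-22, 0.000108, 0.0183 and 0.00130) and none with an estimated correlation (adjusted p = 0.726, 0.856, 0.856 and 0.726).

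Intronic reads with drug were higher in J2 RNA for SDCCAG3 (7.64 ± 0.571 to 61.8 ± 3.07, 3.02 ± 0.11) and PABPC1, a poly(A)-binding protein (3.502 ± 0.469 to 19.7 ± 0.537, 2.49 ± 0.14), and lower for TRIM25, a ubiquitin ligase of RNA sensing (11.5 ± 0.752 to 1.37 ± 0.208, -3.07 ± 0.18). The intronic share of RPS29 went from 10.6% ± 0.634 to 58.5% ± 6.07 (3.58 ± 0.26, limma with Benjamini-Hochberg, adjusted p = 5.66e-05), in intron 1 of 2 (chromosome 14, 49586050 to 49586284). RPL30 went from 20.7% ± 1.43 to 58.6% ± 2.504 (2.44 ± 0.09), with intron 2 of 4 (chromosome 8, 98045089 to 98045346) going from 30.3% to 70.2% intronic. Of 40 ribosomal protein genes the ratio was higher in J2 RNA in 19 (23 adjusted over the list alone) and lower in 1, and in 20 and 1 with median-of-ratios scaling. This list passed by camera with the preset correlation (adjusted p = 7.87e-09) and with an estimated one (adjusted p = 0.0243). Stress response genes were lower in intronic reads (9 of 12, camera adjusted p = 0.00869, and adjusted p = 0.545 with an estimated correlation) and in the ratio (5 of 12, camera adjusted p = 0.0118, and adjusted p = 0.369 with an estimated correlation), with no member higher in either. Spliced reads of 2387 genes were higher and of 2320 lower in J2 RNA, and intronic reads of 1057 and 753. The ratio was higher in 360 and lower in 320 genes, counts that fell to 176 and 123, 156 and 89, 185 and 196, or 203 and 138 without input drug replicate 1, input drug replicate 2, J2 drug replicate 1 or J2 drug replicate 2. Lower intronic reads numbered 472 without input drug replicate 1 and 336 without input drug replicate 2.

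The fifth comparison asked for which RNAs the drug changed recovery by J2 relative to the input. Spliced reads gained in AMD1 (5.43 ± 0.59) and in PLS3, an actin-bundling protein (5.12 ± 0.55), which went from 7.51 ± 0.279 to 2.17 ± 0.419 RPM in the input and from 0.775 ± 0.0784 to 7.79 ± 4.73 in J2 RNA. The J2 drug libraries differed most for spliced reads (chi-square per degree of freedom 16.2), and without J2 drug replicate 1 or 2 the log2 fold changes were 5.92 and 4.68 for AMD1 and 5.63 and 4.31 for PLS3. RPS29 lost recovery (-2.70 ± 0.24), as did RPL31 (-2.16 ± 0.13) and CYCS, cytochrome c (-2.05 ± 0.14). Of 47 ribosomal protein genes 35 lost spliced recovery and 5 gained, against 41 and 1 with median-of-ratios scaling (camera adjusted p = 1.90e-24, and adjusted p = 0.913 with an estimated correlation). Their intronic to spliced ratio gained in 24 of 40 (29 adjusted over the list alone) and lost in 2 (4 adjusted over the list alone), against 21 and 4 (camera adjusted p = 6.30e-06, and adjusted p = 0.0525 with an estimated correlation). Among sensors, DDX58 gained (2.75 ± 0.45), as did EIF2AK2, the RNA-activated kinase (3.42 ± 0.47), ADAR lost (-0.56 ± 0.13), and IFIH1 did not pass (1.38 ± 0.55, edgeR with Benjamini-Hochberg, adjusted p = 0.0596). Spliced recovery rose in 3027 and fell in 1171 of 8461 genes (median 0.28, and 1817 and 2189 with median-of-ratios scaling, median -0.05). With each library's trend over transcript GC content and length removed, 2965 gains and 1150 losses among 8283 genes became 3608 and 767, and 81.6% of gains and 38.1% of losses were kept, or 71.5% and 48.2% with the median effect held as before. Whether the genes named for this comparison kept theirs was not analysed here. Intronic recovery rose in 1027 and fell in 117 of 3992 genes (336 and 409 with that scaling, and 66 falls without input drug replicate 2). The ratio rose in 405 and fell in 218 of 3837 genes, against 224 and 328 with that scaling. Without input drug replicate 1 or 2 or J2 drug replicate 1 or 2 its rises numbered 143, 148, 202 and 169, and its falls 88 without input drug replicate 1, 83 without input drug replicate 2 and 81 without J2 drug replicate 2.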

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

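The tests of 1 J2 drug library, of GC content and length for gains and losses apart and with the median effect held, of retained introns by the ratio, of a shared RNA in both introns, of reads outside them and of exons of other transcripts were chosen after the results were seen, and the other tests before.

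Each result in this part was marked because the drug effect in J2 RNA differed from that in the input by the interaction test of the same fit (edgeR for reads, limma for the ratio, Benjamini-Hochberg adjusted p under 0.05). Spliced reads of 3027 genes gained and of 1171 lost recovery by J2, intronic reads of 1027 gained and of 117 lost, and the intronic to spliced ratio of 405 gained and of 218 lost. In spliced reads gains were called in AMD1 (5.43), PLS3 (5.12), DLG1, a polarity scaffold (4.65), CPD, a carboxypeptidase (4.56), and USP34, a deubiquitinase (4.25), and without J2 drug replicate 2 the first 4 were 4.68, 4.31, 3.77 and 3.91. The mitotic genes CENPE (4.15) and TOP2A (3.43) gained, as did ASNS (3.80), whose spliced reads had fallen in the input, and the sensors EIF2AK2 (3.42) and DDX58 (2.75). Losses were in RPS29 (-2.70), FKBP11, a chaperone (-2.20), RPL31 (-2.16), TM4SF1, a membrane protein (-2.08), CYCS (-2.05), RPL11 (-1.82), RPL37 (-1.78), RPL30 (-1.75), SNRPD3 (-1.71), CAV1, a caveolar protein (-1.40), SRSF3 (-1.35), PHF5A (-1.17), ADAR (-0.56) and SF3B2 (-0.52).

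In intronic reads SMURF2, a ubiquitin ligase (3.51), C5orf22 (2.68) and ATRX, a chromatin remodeller (2.35), gained, and HFM1 (-5.54), SLCO5A1 (-5.40) and SRSF3 (-1.37) lost. Without input drug replicate 1, input drug replicate 2, J2 vehicle replicate 1 or J2 vehicle replicate 2 the values were -3.03, -6.40, -6.34 and -3.59 for HFM1 and -2.86, -6.27, -6.20 and -3.47 for SLCO5A1, and both calls ended with the deposited RPKM (-4.03 and -3.86, limma adjusted p = 0.101 and 0.111). The intronic to spliced ratio gained in RPS29 (3.05), TUBA1C, a tubulin with close paralogs (2.83), RPL31 (2.79) and RPL30 (2.33). It lost in CUL5, a ubiquitin ligase scaffold (-4.61), C6orf62 (-4.06), USP1 (-3.85) and KTN1 (-3.56). The TUBA1C call ended in introns free of other exons. Among gene lists in spliced reads, 35 of 47 ribosomal protein genes lost and 5 gained (camera adjusted p = 1.90e-24, and adjusted p = 0.913 with an estimated correlation). Of 6 SF3b genes 3 lost and none gained (camera adjusted p = 0.0119), and of 35 other spliceosome genes 14 lost and 7 gained (camera adjusted p = 0.00700), against 6 and 0 and 23 and 4 with median-of-ratios scaling. Of 28 SR and hnRNP genes 9 lost (10 adjusted over the list alone) and 7 gained (camera adjusted p = 0.0385), and their median was 0.04, or -0.30 with that scaling. None of these 3 calls stood without J2 drug replicate 1 (camera adjusted p = 0.105, 0.105 and 0.273) or with an estimated correlation (adjusted p = 0.985 each), and the counts of the others were the same adjusted over the list alone. In the ratio, 24 of 40 ribosomal protein genes gained and 2 lost (29 and 4 adjusted over the list alone, camera adjusted p = 6.30e-06, and adjusted p = 0.0525 with an estimated correlation).

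The first pattern weighed was the changed recovery of spliced reads by J2. The tables argue against 1 J2 drug library as the source of the calls of single genes. Leaving out either kept at least 99.0% of the number of calls (4633 without replicate 1 and 4157 without replicate 2, of 4198), and at least 90.97% of the calls in the same genes and direction (4027 and 3819). The 3 list calls that ended without J2 drug replicate 1 are not covered by this. For a rise of intronic reads of the same gene, the interaction of 1 replicate pair was set against the intronic drug effect of the other pair. The Spearman correlation was -0.0182 or -0.0267 across 3837 genes, so no positive link was seen. The interaction subtracts the spliced drug effect in the input, which went with the intronic one across genes (Spearman 0.224). That pulls the correlation down, so the value does not decide. With the drug effect on the intronic to spliced ratio the correlation was 0.149 or 0.0997. This does not decide either, because the spliced drug effect in the input enters both the ratio and the interaction. With the trends over transcript GC content and length removed from each library, 2965 gains and 1150 losses became 3608 and 767, and the median effect moved from 0.28 to 0.43. Of gains 81.6% were kept and of losses 38.1%, and 71.5% and 48.2% with the median effect held as before. GC content and length may therefore account for part of the losses, and the gains are left undecided, as are both together (69.4% kept). The Spearman correlation with transcript length alone was 0.241, which lies between the bounds set before the test and does not decide either. A change of RNA structure with the drug stays open and was not tested, as the files hold no sequence-level data.

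The second pattern was the intronic reads of SLCO5A1 (chromosome 8, 69682344 to 69705030, GRCh38) and HFM1 (chromosome 1, 91385835 to 91394092) in input drug replicate 1, at 5763 and 3036 RPM against 542 and 293 in replicate 2. Reads in the SLCO5A1 intron varied 85.6-fold in RPM across the 8 libraries, and those in the HFM1 intron ran from 37.7 to 3036 RPM. The ratio of the reads in the 2 introns stayed between 1.71 and 2.01, a range of 1.17-fold. The tables argue against higher transcription of the 2 genes, since reads outside these introns came to 0.00266% of those inside (11 against 413545). The test chosen before, a fold of the other listed introns of both genes, gave no value. Those introns held 0 reads in input drug replicate 1 and 0 in replicate 2. A candidate explanation is 1 RNA from elsewhere whose reads are placed in both introns. The small RNA pseudogene RN7SKP29 is annotated on the other strand of the SLCO5A1 intron. The HFM1 intron holds no annotated exon of another gene, so the annotation names no RNA common to both. The source of such an RNA was not tested, as no reads or genome sequence were at hand.

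The third pattern was the 260 genes whose intronic reads fell with drug in the input. In introns free of other exons 84.6% of these falls were lost, against 38.3% of 3127 rises, which is consistent with exons of other transcripts inside the counted introns as a source of many falls. Most of that loss was of genes no longer testable, since of 75 falls still tested 40 remained called (53.3%), against 1928 of 1955 rises (98.6%). Spliced reads also fell in 74.1% of the falling genes tested for both (169 of 228), against 48.7% of all genes tested, so a lower amount of the same gene's RNA may account for part. Both explanations stay open and the tests do not part them.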

How the results depend on the processing

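The alternatives with DESeq2, TMM, limma on log2 of RPM, introns free of other exons, edgeR on both kinds of read, the median over introns, the sets without SLCO5A1 and HFM1 and the filters, scaling, block and left-out libraries for the structure trend, and the removal of trends over GC content and length, were chosen after the data were seen, and the others before. At the depth of the libraries, 8461 of 15902 listed genes passed the filter for spliced reads and 3992 for intronic reads. Depth scaling keeps a general rise of intronic reads, and median-of-ratios, TMM and DESeq2 remove it by construction. Counts, lists, shares and trends stayed near the reported value in 292 cases over the alternatives that leave out no library, and moved, weakened, grew or reversed in 39, 88, 49 and 2. Medians and shares of calls were the same in 251 cases and moved in 87, and with a library left out in 237 and 3. Values of named genes were the same in 2215 cases, weaker in 10 and reversed in 6. Lower counts where fewer genes are tested, higher counts where more are, and shifts where scaling sets the median near 0 follow from how the alternatives are built. For every other result that changed, the cause was not tested. A planned single-exon comparison, the mitochondrial share and FPKM values could not be had, as the files list introns only, so their alternatives were not run.

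For reference, the reported rises and falls numbered 1841 and 4118 for drug in the input, 2927 and 3344 for drug in J2 RNA, 1386 and 3746 for J2 against input with vehicle, 2387 and 2320 for J2 against input with drug and 3027 and 1171 for the interaction in spliced reads. They numbered 3127 and 260 for drug in the input, 3342 and 229 for drug in J2 RNA, 313 and 1174 for J2 against input with vehicle, 1057 and 753 for J2 against input with drug and 1027 and 117 for the interaction in intronic reads. For the ratio they numbered 3212 and 88 for drug in the input, 3203 and 131 for drug in J2 RNA, 424 and 806 for J2 against input with vehicle, 360 and 320 for J2 against input with drug and 405 and 218 for the interaction.

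Median-of-ratios scaling gave 3178 rises in spliced reads for drug in the input, 3049 rises and 2280 falls in spliced reads for J2 against input with vehicle, 1817 rises and 2189 falls in spliced reads for the interaction. Further counts were 1340 rises and 1366 falls in intronic reads for drug in the input, 1422 rises and 1390 falls in intronic reads for drug in J2 RNA, 856 rises and 539 falls in intronic reads for J2 against input with vehicle. Further counts were 336 rises and 409 falls in intronic reads for the interaction. For the intronic to spliced ratio, this scaling gave 1314 rises and 1208 falls in the ratio for drug in the input, 1337 rises and 1296 falls in the ratio for drug in J2 RNA, 643 rises and 483 falls in the ratio for J2 against input with vehicle, 224 rises and 328 falls in the ratio for the interaction. Lists past the threshold in intronic reads numbered 0 for drug in the input (against 1) and 0 for drug in J2 RNA (against 1), with ribosomal protein genes at adjusted p = 0.205 and 0.715 by camera. TMM scaling gave 1362 rises and 1341 falls in intronic reads for drug in the input, 1403 rises and 1406 falls in intronic reads for drug in J2 RNA, 2521 rises in spliced reads and 821 rises and 569 falls in intronic reads for J2 against input with vehicle. Further counts were 299 rises and 449 falls in intronic reads for the interaction. DESeq2 gave 2967 rises and 2731 falls in spliced reads and 1187 rises and 1255 falls in intronic reads for drug in the input, 1303 rises and 1315 falls in intronic reads for drug in J2 RNA. Further counts were 2834 rises and 2070 falls in spliced reads and 730 rises and 447 falls in intronic reads for J2 against input with vehicle, 1642 rises and 1936 falls in spliced reads and 245 rises and 287 falls in intronic reads for the interaction. The intronic reads of IFIH1 with drug in J2 RNA, which had risen by 1.97 on the log2 scale, went to -0.19 with median-of-ratios scaling, -0.20 with TMM and -0.19 with DESeq2. The spliced reads of KRT18 with drug in the input (-0.41) went to 0.00279 with median-of-ratios scaling and 0.00279 with DESeq2. Those of DDX58 (-0.87) went to -0.46 with median-of-ratios scaling, -0.59 with TMM and -0.46 with DESeq2 and were no longer called (adjusted p from 0.0875 to 0.2497). KIAA1467 lost its call in intronic reads for J2 against input with drug in DESeq2, with a log2 fold change of -5.49 against -5.40 (adjusted p = 0.0979).

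A minimum of 5 RPM, with fewer genes tested, gave 1156 rises and 63 falls in intronic reads and 1120 rises and 23 falls in the ratio for drug in the input, 1869 rises in spliced reads, 1191 rises and 53 falls in intronic reads and 1115 rises and 23 falls in the ratio for drug in J2 RNA. Further counts were 2350 falls in spliced reads, 193 rises and 419 falls in intronic reads and 179 rises and 338 falls in the ratio for J2 against input with vehicle, 636 rises and 231 falls in intronic reads and 232 rises and 123 falls in the ratio for J2 against input with drug. Further counts were 596 rises and 68 falls in intronic reads and 255 rises and 82 falls in the ratio for the interaction. Spearman correlations of the log2 fold change across genes became -0.294 with number of introns and 0.0187 with gene length (spliced reads, drug in the input), 0.156 with number of introns and -0.0448 with gene length (the ratio, drug in the input), -0.0864 with number of introns and 0.199 with gene length (spliced reads, drug in J2 RNA), 0.0621 with number of introns and -0.154 with gene length (the ratio, drug in J2 RNA), 0.197 with gene length (spliced reads, the interaction), -0.149 with number of introns and -0.263 with gene length (the ratio, the interaction). No filter, with more genes tested, gave 401 falls in intronic reads and 5044 rises and 183 falls in the ratio for drug in the input, 5112 rises and 380 falls in intronic reads and 4872 rises and 400 falls in the ratio for drug in J2 RNA. Further counts were 147 rises and 131 falls in the ratio for the interaction. The correlations became -0.182 with number of introns and -0.00211 with gene length (spliced reads, drug in the input), 0.211 with number of introns and -0.0929 with gene length (the ratio, drug in the input), 0.00506 with number of introns and 0.177 with gene length (spliced reads, drug in J2 RNA), 0.107 with number of introns and -0.197 with gene length (the ratio, drug in J2 RNA), 0.169 with number of introns and 0.166 with gene length (spliced reads, the interaction), -0.0927 with number of introns and -0.145 with gene length (the ratio, the interaction), so that the weak trends of spliced reads with gene length in the input and with the number of introns in J2 RNA changed sign.

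Introns free of other exons, with fewer genes tested, gave 2015 rises and 50 falls in intronic reads and 1999 rises and 12 falls in the ratio for drug in the input, 2059 rises and 44 falls in intronic reads and 1957 rises and 19 falls in the ratio for drug in J2 RNA. Further counts were 128 rises and 565 falls in intronic reads and 170 rises and 430 falls in the ratio for J2 against input with vehicle, 618 rises and 362 falls in intronic reads and 84 rises and 78 falls in the ratio for J2 against input with drug. Further counts were 527 rises and 40 falls in intronic reads and 162 rises and 66 falls in the ratio for the interaction. Intronic shares there were 1.67% for input with vehicle, 8.44% for input with drug, 1.39% for J2 with vehicle and 9.18% for J2 with drug. The intronic reads of RRBP1 with drug in the input reversed from -1.17 to 1.94, where an exon of the gene itself lies in the intron left out. The intronic reads of HUWE1 for J2 against input with vehicle went from -2.85 to -0.53 (edgeR adjusted p = 0.348) and the ratio of TUBA1C in the interaction from 2.83 to 1.55 (limma adjusted p = 0.0609). In introns of at least 100 bases the share was 4.100% for input with vehicle and 4.11% for J2 with vehicle. Over genes of at least 5 RPM in every group it was 3.31% for input with vehicle, 3.39% for J2 with vehicle and 12.03% for J2 with drug. As a median over introns it was 0.0257% for input with vehicle, 2.59% for input with drug, 0% for J2 with vehicle and 1.92% for J2 with drug. Introns at 10% or more came to 12.1% for input with vehicle, 30.4% for input with drug, 10.6% for J2 with vehicle and 28.4% for J2 with drug. Without SLCO5A1 and HFM1 the share was 3.699% for input with vehicle. In each of these settings both drug groups lay above both vehicle groups.

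The deposited RPKM, tested with limma, gave 122 falls in intronic reads for drug in the input, 82 falls in intronic reads for drug in J2 RNA, 92 rises and 341 falls in intronic reads for J2 against input with vehicle, 393 falls in intronic reads for J2 against input with drug. Further counts were 579 rises and 70 falls in intronic reads for the interaction. HFM1 and SLCO5A1 lost their calls in the interaction there, at -4.03 and -3.86 against -5.54 and -5.40 (adjusted p = 0.101 and 0.111). With limma on log2 of RPM + 1 there were 271 falls in intronic reads for the interaction, and with edgeR on both kinds of read 582 rises and 607 falls in the ratio for J2 against input with drug. Without the trend in limma there were 235 rises and 140 falls in the ratio for the interaction, and in fits on the compared groups alone 245 rises and 410 falls in the ratio for J2 against input with vehicle and 569 rises and 522 falls in the ratio for J2 against input with drug. With an estimated correlation in camera, lists past the threshold numbered in spliced reads 0 for drug in the input (against 6), 0 for J2 against input with drug (against 4) and 0 for the interaction (against 4), in intronic reads 0 for drug in the input (against 1), 0 for drug in J2 RNA (against 1), 0 for J2 against input with vehicle (against 2) and 0 for J2 against input with drug (against 1), in the ratio 0 for J2 against input with vehicle (against 1), 1 for J2 against input with drug (against 2) and 0 for the interaction (against 1). With fry, which does not compare a list with other genes, they numbered in spliced reads 10 for drug in the input (against 6), 7 for drug in J2 RNA (against 0), 10 for J2 against input with vehicle (against 0) and 7 for J2 against input with drug (against 4), in intronic reads 14 for drug in the input (against 1), 14 for drug in J2 RNA (against 1), 11 for J2 against input with vehicle (against 2), 7 for J2 against input with drug (against 1) and 6 for the interaction (against 0), in the ratio 13 for drug in the input (against 0), 13 for drug in J2 RNA (against 0), 9 for J2 against input with vehicle (against 1), 4 for J2 against input with drug (against 2) and 8 for the interaction (against 1). The libraries share only a number, and deviations from the group means in libraries of the same number correlated between -0.0905 and 0.128, which does not show that the numbers pair them, and a pairing was not excluded. A replicate block gave 2958 rises and 1140 falls in spliced reads for the interaction, with 206 of 206 values of named genes the same. The SR and hnRNP list lost its call in spliced reads for the interaction with that block (camera adjusted p = 0.0566). A replicate block within each treatment, so that input and J2 of 1 number share a block, gave 282 rises and 148 falls in the ratio for the interaction, with 417 of 623 calls shared, and 82 of 82 values of named genes the same.

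Leaving out each library in turn, where the lone sample left in a group is assumed to vary like the other groups, moved falls in the ratio for J2 against input with vehicle from 532 to 838, falls in intronic reads for J2 against input with drug from 336 to 795, rises in the ratio for J2 against input with drug from 156 to 458, falls in the ratio for J2 against input with drug from 89 to 418. It moved falls in intronic reads for the interaction from 66 to 109, rises in the ratio for the interaction from 143 to 545, falls in the ratio for the interaction from 81 to 216. These counts changed more than 1.5-fold: falls in the ratio for J2 against input with vehicle without input vehicle 1, falls in intronic reads for J2 against input with drug without input drug 1 and input drug 2, rises in the ratio for J2 against input with drug without input drug 1, input drug 2, J2 drug 1 and J2 drug 2, falls in the ratio for J2 against input with drug without input drug 1, input drug 2, J2 drug 1 and J2 drug 2, rises in the ratio for the interaction without input drug 1, input drug 2, J2 drug 1 and J2 drug 2, falls in the ratio for the interaction without input drug 1, input drug 2 and J2 drug 2, falls in intronic reads for the interaction without input drug 2. Lists past the threshold ran from 1 to 4 in spliced reads for the interaction, from 0 to 1 in the ratio for drug in the input and from 1 to 2 in the ratio for the interaction. In spliced reads the interaction lost the SF3b, SR and hnRNP, and other spliceosome lists without J2 drug 1 (camera adjusted p = 0.105, 0.273 and 0.105), and the SR and hnRNP list also without input vehicle 1, input vehicle 2 or J2 vehicle 1 (adjusted p = 0.0654, 0.0521 and 0.05497). Spearman correlations ran -0.266 to -0.255 with number of introns (spliced reads, drug in the input), 0.00845 to 0.0286 with gene length (spliced reads, drug in the input), 0.164 to 0.173 with number of introns (the ratio, drug in the input), -0.131 to -0.1205 with gene length (the ratio, drug in the input), -0.0387 to -0.00231 with number of introns (spliced reads, drug in J2 RNA). They ran 0.197 to 0.245 with gene length (spliced reads, drug in J2 RNA), 0.06595 to 0.0864 with number of introns (the ratio, drug in J2 RNA), -0.224 to -0.213 with gene length (the ratio, drug in J2 RNA), 0.194 to 0.231 with gene length (spliced reads, the interaction), -0.128 to -0.0891 with number of introns (the ratio, the interaction), -0.192 to -0.173 with gene length (the ratio, the interaction). Counts, lists, shares and trends were the same in 419 cases of a library left out, and values of named genes in 1629, with 5 weaker (KRT18 and DDX58) and none reversed.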

Other observations

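No test in this part was chosen after the results were seen, and its values are given without explanation.

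Gene lists outside the main comparisons were counted in the same way, with counts under median-of-ratios scaling where they differ in direction. In spliced reads of the input with drug, apoptosis regulators rose in 8 and fell in 5 of 16 genes, with BCL2L1 up (0.81 ± 0.11) and BAK1 down (-1.03 ± 0.06). Genes of DNA replication and repair rose in 4 and fell in 12 of 28, such as CDC6 (-3.01 ± 0.18) and POLD1 (-1.75 ± 0.09), against 11 and 6 with that scaling. Targets of p53 rose in 3 and fell in 6 of 16, such as CDKN1A (-1.58 ± 0.12), with 6 and 6 under that scaling. Immediate-early genes rose in 4 and fell in 3 of 13, such as CTGF (1.14 ± 0.16). Genes reported with edited Alu repeats rose in 3, such as PSMB2 (0.76 ± 0.10), and fell in 5 of 9, such as NUP43 (-2.67 ± 0.38). Nonsense-mediated decay factors rose in 5, such as EIF4A3 (1.29 ± 0.09), and fell in 7 of 14, such as SMG9 (-1.40 ± 0.11), against 7 and 4. Mesenchymal and basal markers rose in 6, such as CAV1 (1.10 ± 0.09), and fell in 5 of 14, such as AXL (-0.73 ± 0.05). Counts adjusted over the list alone were the same for these 7 lists. None of them stood apart from other genes by camera (adjusted p from 0.176 to 0.787), while under median-of-ratios scaling the mesenchymal and basal markers, with 9 rising and 4 falling, stood above other genes (adjusted p = 0.0406).

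In J2 RNA with drug, spliced reads of the integrated stress and unfolded protein response list rose in 2 and fell in 14 of 24 genes. The phosphatase subunit PPP1R15A was among the rises (1.09 ± 0.05), and ATF4, the transcription factor of the response, had an intronic to spliced ratio that rose by 5.39 ± 0.34. The decay kinase SMG1 rose (2.51 ± 0.18), the splicing factor U2AF2 rose (1.09 ± 0.05), and its partner SF1 fell (-1.68 ± 0.08). The list did not stand apart by camera (adjusted p = 0.800), and its counts were the same adjusted over the list alone and with median-of-ratios scaling.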
